A study of Mus musculus with 26 samples.

How the data were processed

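Libraries were made from TRIzol RNA with the TruSeq RNA kit and sequenced on a NextSeq 500, per the labels' protocols. Reads were handled with bcl2fastq, Bowtie2 and RSEM against mm10, with no versions given, per the submitters' processing notes. The library kit as labelled does not mark strand, and the read length and depth were not used. The deposited values were a normalised score rather than counts, as made by the authors. Sorted values were equal between libraries to within 2 at every rank, library totals ran from 4619641 to 4624161, and 10 genes in each library shared the highest value of 21544. The table held 18198 genes, of which 18039 were matched to a gene symbol of the GRCm38 build and 159 were not, and 0 sample columns were left unused. Of 10 housekeeping genes checked, 0 were at 0 in any library, while 15 genes stood at 0 in some library despite a median of at least 500, so such values are described as listed at 0. The correlation between replicates was lowest for MEF (0.9253) and highest for iPSC (0.9602). Replicates were used as independent in the fit, because the labels did not pair them across groups and no group had 3 libraries.

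Identities were taken from the GRCm38 (mm10) annotation, in which each of the following is protein coding. Pou5f1 is ENSMUSG00000024406 at chromosome 17:35506018-35510772, Sox2 is ENSMUSG00000074637 at chromosome 3:34650405-34652461, and Klf4 is ENSMUSG00000003032 at chromosome 4:55527143-55532466. Myc is ENSMUSG00000022346 at chromosome 15:61985391-61990374, Jun is ENSMUSG00000052684 at chromosome 4:95049034-95052222, and Sap30 is ENSMUSG00000031609 at chromosome 8:57482707-57487860.

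The groups, the comparisons, the gene lists and the tests of genes and lists were chosen before the data were examined, as were the alternatives other than those named as added later. The design assumed counts, and because the unit was a score the limma test fixed for that case was used. Values plus 1 were taken to log2, genes with a value of at least 10 in at least 2 libraries were tested (16038), and limma 3.58.1 in R 4.3.3 was fitted to all 26 libraries with 1 mean per group, with moderated variances that followed mean expression and were robust to extreme genes (statmod 1.5.0). A gene was called at a Benjamini-Hochberg adjusted p from limma below 0.05 with a log2 fold of at least 1, and every adjusted p given for a gene is that of limma. The interaction tested whether the fold from day 0 to day 7 differed between OSK+cJun and OSK. Tables were read with data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

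Gene lists were tested with camera in limma at a preset correlation of 0.01 between genes, with p adjusted over 512 tests, of which 184 were called, and 25 of these with a correlation estimated from the data. The 27 lists were pluripotency, epithelial, mesenchymal, fibroblast extracellular matrix, contractile smooth muscle, AP-1 without Jun, proliferation, p53 and senescence, inflammatory factors, interferon response, Sin3 complex without Sap30, polycomb and DNA methylation, genes of the two-cell stage, germline, primed pluripotency and mesendoderm, primitive endoderm, trophoblast, keratinocyte, neural, macrophage and blood, endothelial, skeletal and cardiac muscle, glycolysis, oxidative phosphorylation, cholesterol synthesis, Hox and imprinted genes. The mesenchymal list held regulators and also markers such as Cdh2, Cdh11, Vim, Fn1, S100a4 and Thy1. The extracellular matrix list also held the receptor gene Pdgfrb and the membrane protease gene Fap, and the contractile list Ccn1 and Ccn2. Class names in the results stand for these lists, and not every member is of the class named. Genes high in MEF (1526) or in ESC (1266) were those called between them with a log2 fold of at least 3, and the position of a library was the mean over genes of its log2 value, scaled from MEF to ESC.

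Pou5f1, Sox2, Klf4, Myc, Jun and Sap30 were always looked at. Other genes were named from the 8 largest increases and 8 largest decreases that had an adjusted p below 0.05, a mean of at least 10 per 1000000 of the library total in the higher group and libraries of the groups that did not overlap, leaving out model, clone and pseudogene symbols. For the interaction the highest mean of its groups was used, and no rule on overlap of libraries was applied. For lists, up to 4 members with the smallest adjusted p were considered, or the most highly expressed members where the list did not change. Clauses on what a gene does come from general knowledge and not from these data. In simulations with the same layout, 41 to 87 percent of 100 genes changed by a log2 fold of 1.5 were recovered and 88 to 100 percent of those changed by 3, with 3 to 17 of the unchanged genes called among 16038. The lowest recoveries, 41 and 88 percent, were those of the interaction. Changed genes were drawn from the more highly expressed ones and noise was independent between libraries, so recovery of genes with low values was not measured. Each gene was given the same spread in all groups, as the fit assumes. False calls where spread differs between groups were therefore not measured. In the list simulation the 1 shifted list of 20 genes was called with either correlation, and 0 of 27 unshifted lists were. Its genes varied independently of each other, so it does not show how the list test behaves where genes are correlated.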

Results

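The table held deposited expression values for 18198 genes in 26 mouse libraries, 2 for each of 13 groups. The groups were embryonic fibroblasts (MEF), embryonic stem cells (ESC), induced pluripotent stem cells (iPSC), fibroblasts given Pou5f1, Sox2 and Klf4 (OSK) at days 0, 1, 3, 5 and 7, the same factors with Jun (OSK+cJun) at days 0, 1, 3 and 7, and OSK with a hairpin against Sap30 (OSK+shSap30) at day 7. Sequencing depth could not be read from the values, which had been forced to the same distribution in every library, and the labels did not say whether replicates were separate cultures, so they may be technical. Every comparison had n = 2 libraries per group, folds are log2 folds of the mean of log2(value+1), and folds of genes with values near 0 are understated on that scale.

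Sap30, which encodes a subunit of the Sin3 deacetylase complex, stood at 20 and 41 in the OSK+shSap30 libraries, against 301 and 378 in OSK day 7, and so dropped by 3.51 (SE 0.32, adjusted p = 1.33e-05). Its values in the OSK course were 82 and 91 at day 0, 83 and 80 at day 1, 93 and 140 at day 3 and 148 and 207 at day 5. With added Jun, Sap30 was 77 and 107 at day 0, 53 and 47 at day 1, 62 and 60 at day 3 and 74 and 93 at day 7, while MEF had 67 and 36, iPSC 424 and 433 and ESC 328 and 343. Jun, a subunit of the AP-1 transcription factor, stood at 4616 and 5023 at day 0, 6929 and 6123 at day 1, 7721 and 6929 at day 3 and 8981 and 6124 at day 7 of OSK+cJun. Without added Jun the same gene was 875 and 620 at day 0, 468 and 340 at day 1, 536 and 425 at day 3, 321 and 385 at day 5, 1010 and 582 at day 7, 444 and 726 with the hairpin, 983 and 554 in MEF, 297 and 355 in iPSC and 13 and 31 in ESC. Transcripts from the delivered vectors and from the endogenous Pou5f1, Sox2, Klf4 and Jun genes may not be separable in these values.

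**Figure D1:**
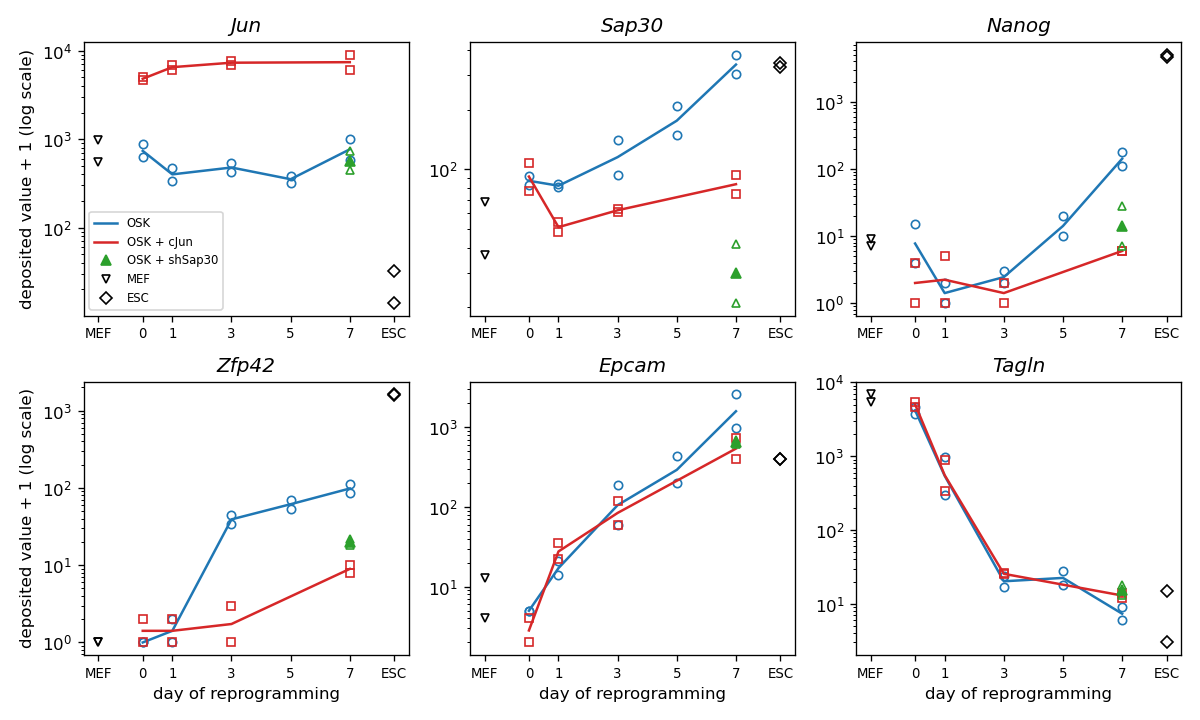
Values plus 1 of Jun, Sap30, Nanog, Zfp42, Epcam and Tagln on a log axis by day, with MEF and ESC at the sides. Open points are libraries (n = 2 per group), lines join geometric means and the filled triangle is the geometric mean of OSK+shSap30.

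ESC differed from MEF by gain of pluripotency genes and loss of fibroblast genes. Pou5f1, a core pluripotency factor, was higher by 11.50 (SE 0.97, adjusted p = 4.83e-08), with values of 5015 (SD 0.707) against 1 (SD 1.41). Esrrb and Tfcp2l1, transcription factors of naive pluripotency, were higher by 10.90 (SE 0.94, adjusted p = 3.41e-08) and 10.58 (SE 0.95, adjusted p = 9.61e-08), and Sox2 by 9.14 (SE 0.48, adjusted p = 1.19e-10). Tdh, a threonine-catabolic enzyme used by mouse ESC, was higher by 10.84 (SE 0.61, adjusted p = 1.75e-10), and Zfp42, Fgf4 and Tdgf1 were listed at 0 in MEF and had values of 1601 (SD 47.4), 1345 (SD 0.707) and 1270 (SD 481) in ESC. The proteoglycan gene Bgn fell by 10.73 (SE 1.17, adjusted p = 8.75e-07), the matricellular Thbs1 fell by 10.64 (SE 1.01, adjusted p = 1.69e-07) and the smooth-muscle actin Acta2 fell by 10.57 (SE 0.86, adjusted p = 3.14e-08). Thbs1 and Acta2 stood at 21544, the highest value of the table, in both MEF libraries, so these folds may be understated. Jun fell by 5.13 (SE 0.37, adjusted p = 3.76e-09), Myc fell by 4.90 (SE 0.83, adjusted p = 9.4e-05), and Sap30 rose by 2.75 (SE 0.32, adjusted p = 1.17e-06). In total 6896 of 16038 tested genes were called, 3586 higher and 3310 lower in ESC, and the median gene shifted by 0.128. Klf4 rose by 1.66 (SE 0.50, adjusted p = 0.00908), a call lost without ESC replicate 2 (1.20) or MEF replicate 2 (1.21).

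The pluripotency list rose in ESC, with 28 of 28 members called, and 28 with p adjusted over the list alone (camera adjusted p = 5.91e-16, adjusted p = 0.00473 with an estimated correlation). L1td1 rose by 10.15. Hox genes, which keep positional identity in fibroblasts, fell in 24 of 25, 24 over the list alone (camera adjusted p = 5.02e-11, adjusted p = 0.0276 with an estimated correlation). Hoxc6 was at -6.13 and Hoxc8 at -6.14. All 25 tested extracellular matrix genes fell, 25 over the list alone (camera adjusted p = 1.97e-17, adjusted p = 0.11 with an estimated correlation). The elastic-fibre gene Fbln2 was at -7.27 and Col5a2 at -6.72. Mesenchymal genes fell in 22 of 23, 22 over the list alone (camera adjusted p = 1.09e-14, adjusted p = 0.0574 with an estimated correlation). The cadherin Cdh11 was at -7.80 and Cdh2 at -4.44. Contractile genes fell in 13 of 13, 13 over the list alone (camera adjusted p = 8.23e-10, adjusted p = 0.11 with an estimated correlation). Tpm1 was at -5.46. Epithelial genes rose in 18 of 21 and fell in 1, Krt19, 19 and 1 over the list alone (camera adjusted p = 1.19e-06, adjusted p = 0.148 with an estimated correlation). Spint1 rose by 8.95 and Cdh1 by 8.80. AP-1 genes other than Jun fell in 10 of 12, 10 over the list alone (camera adjusted p = 0.000209, adjusted p = 0.262 with an estimated correlation). Fosl2 was at -8.32. Imprinted genes fell in 13 of 18 and rose in 1, Snrpn, 13 and 1 over the list alone (camera adjusted p = 5.07e-05, adjusted p = 0.0554 with an estimated correlation). The growth inhibitor Cdkn1c was at -6.77. Germline genes rose in 10 of 12, 10 over the list alone (camera adjusted p = 0.00334, adjusted p = 0.0554 with an estimated correlation). Tuba3a rose by 7.93.

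iPSC had the pluripotency genes that MEF lacked. Pou5f1 was higher by 11.38 (SE 0.97, adjusted p = 1.23e-07), Esrrb by 10.93 (SE 0.94, adjusted p = 8.1e-08) and L1td1, an RNA-binding protein of pluripotent cells, by 10.77 (SE 0.30, adjusted p = 1.38e-13). Tdh was higher by 10.48 (SE 0.61, adjusted p = 1.29e-09), Sox2 by 9.58 (SE 0.48, adjusted p = 4.25e-10), Klf4 by 2.85 (SE 0.50, adjusted p = 0.00015) and Sap30 by 3.10 (SE 0.32, adjusted p = 5.23e-07). Eln, the elastin gene, fell by 7.90 (SE 0.82, adjusted p = 6.11e-07) and the secreted Crispld2 fell by 7.38 (SE 0.92, adjusted p = 3.98e-06), while Angpt1 was listed at 0 in iPSC and at 114 (SD 20.5) in MEF. The pluripotency list rose in 28 of 28, 28 over the list alone (camera adjusted p = 2.46e-19, adjusted p = 0.0033 with an estimated correlation). Tfcp2l1 rose by 10.07. Hox genes fell in 25 of 25, 25 over the list alone (camera adjusted p = 6.81e-12, adjusted p = 0.0267 with an estimated correlation). Hoxb6 was at -5.53 and Hoxb4 at -3.70. Glycolytic genes rose in 11 of 15, 11 over the list alone (camera adjusted p = 7.64e-05, adjusted p = 0.243 with an estimated correlation). Pfkp rose by 2.83 and Hk2 by 2.40. In total 6409 genes were called, 3245 higher and 3164 lower in iPSC. Jun fell by 1.18 (SE 0.37, adjusted p = 0.0128), a call lost without MEF replicate 1 (-0.77) or iPSC replicate 1 (-1.05).

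Against ESC, iPSC had higher values of fibroblast genes. Xist, at 1615 and 3617 in MEF, stood at 174 and 309 in iPSC against 26 and 31 in ESC, and 340 abundant genes high in MEF kept a median of 6.9 percent of the MEF value in iPSC with the ESC value subtracted, 4.96 in replicate 1 and 8.85 in replicate 2. The labels did not say whether feeder fibroblasts were present. They gave passages 5 to 8 for iPSC and 20 to 24 for ESC, so passage cannot be told apart from cell type here. Thbs1 was higher in iPSC by 7.94 (SE 1.01, adjusted p = 5.62e-05), with 3612 (SD 2005) against 31 (SD 41), and Bgn by 7.64 (SE 1.17, adjusted p = 0.000373). Col12a1, a fibril-associated collagen, was higher by 7.20 (SE 0.74, adjusted p = 5.82e-06), the collagen cross-linking enzyme gene Lox by 6.96 (SE 0.91, adjusted p = 8.05e-05), Tnc by 6.55 (SE 0.85, adjusted p = 7.31e-05) and Jun by 3.94 (SE 0.37, adjusted p = 1.39e-06). Dnm3os, a noncoding transcript of mesenchyme, was listed at 0 in ESC and at 143 (SD 27.6) in iPSC. Fyb, an adaptor of immune cells, fell by 4.70 (SE 0.86, adjusted p = 0.00171) and Prrt3 fell by 3.99 (SE 0.70, adjusted p = 0.00109), and Pof1b and Kcnip4 were listed at 0 in iPSC with 116 (SD 31.1) and 56 (SD 4.24) in ESC. Extracellular matrix genes rose in 22 of 25, 23 over the list alone (camera adjusted p = 2.45e-36, adjusted p = 0.0299 with an estimated correlation). Col6a2 rose by 6.09 and Timp3 by 6.10. Mesenchymal genes rose in 15 of 23, 18 over the list alone (camera adjusted p = 9.24e-19, adjusted p = 0.0391 with an estimated correlation). Tgfb2 rose by 3.47 and Runx1 by 4.45. The contractile list rose in 8 of 13, 10 over the list alone (camera adjusted p = 3.94e-14, adjusted p = 0.0554 with an estimated correlation). Tagln rose by 5.73. Inflammatory factors rose in 8 of 17, 11 over the list alone (camera adjusted p = 1.34e-07, adjusted p = 0.112 with an estimated correlation). The macrophage growth factor Csf1 rose by 5.49.

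Pluripotency genes did not differ as a list between iPSC and ESC, with 1 of 28 called, 1 over the list alone (camera adjusted p = 0.39, adjusted p = 0.704 with an estimated correlation). Outside the list, Pou5f1 differed by -0.12 (SE 0.97, adjusted p = 1), Sox2 by 0.44 (SE 0.48, adjusted p = 0.724), Klf4 by 1.18 (SE 0.50, adjusted p = 0.199) and Sap30 by 0.35 (SE 0.32, adjusted p = 0.646), all short of the call. The pooled SEs of Pou5f1, Sox2 and Klf4 were widened by the OSK day 5 replicates, which stood apart. Myc was called, higher in iPSC by 3.17 (SE 0.83, adjusted p = 0.0259), with 121.5 (SD 41.7) against 16.5 (SD 16.3). Dnmt3l, a cofactor of DNA methylation, was the called member at 3.34 (SE 0.70, adjusted p = 0.0051), lost without ESC replicate 2 (2.89) or iPSC replicate 1 (3.05) and with 0.1 in place of 1 added (3.37). AP-1 genes other than Jun rose in 6 of 12, 9 over the list alone (camera adjusted p = 4.03e-07, adjusted p = 0.141 with an estimated correlation). Fosl2 rose by 5.41. The 998 called genes, 733 higher and 265 lower in iPSC, became 536 without iPSC replicate 2 and 376 with spread estimated from the compared libraries alone.

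**Figure D2:**
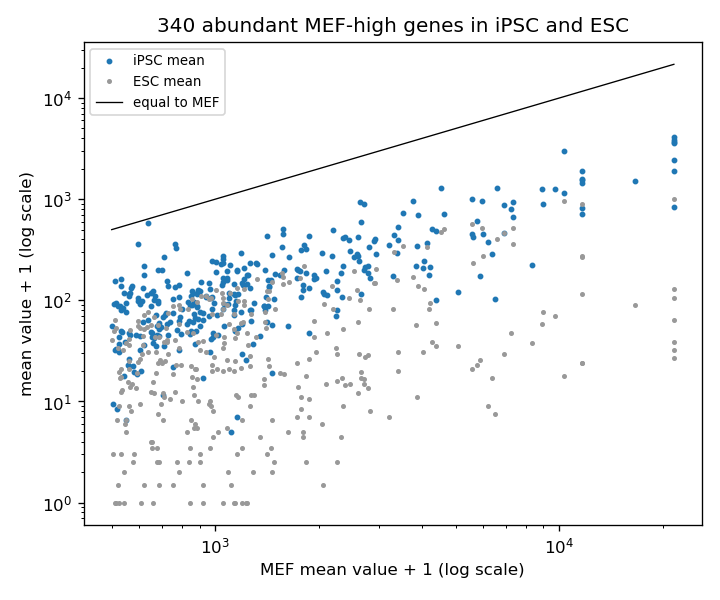
Mean value plus 1 in iPSC and in ESC against MEF for 340 abundant genes high in MEF, on log axes. The line marks values equal to MEF, and each mean is of n = 2 libraries.

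OSK day 0 differed from MEF first by the delivered factors. Pou5f1 was higher by 12.53 (SE 0.97, adjusted p = 4.14e-07), with 10318 (SD 1901) against 1 (SD 1.41), Sox2 by 10.22 (SE 0.48, adjusted p = 1.06e-09) and Klf4 by 4.08 (SE 0.50, adjusted p = 4.96e-05). Scg5, a chaperone of secretory granules, was higher by 8.18 (SE 0.71, adjusted p = 1.44e-06), and Ceacam1 was listed at 0 in MEF with 217 (SD 5.66) at day 0. Ptn, a secreted growth factor, fell by 5.73 (SE 0.58, adjusted p = 7.39e-06), Eln fell by 5.67 (SE 0.82, adjusted p = 0.000232), the growth-factor binder Igfbp5 fell by 5.23 (SE 0.64, adjusted p = 5.92e-05) and the stress pseudokinase Trib3 fell by 5.04 (SE 0.53, adjusted p = 9.34e-06). Jun did not change (adjusted p = 1), with 748 (SD 180) against 769 (SD 303), and Sap30 differed by 0.80 (SE 0.32, adjusted p = 0.14), short of the call but called without MEF replicate 1 (1.24). Extracellular matrix genes fell in 5 of 25, 7 over the list alone (camera adjusted p = 0.00157, adjusted p = 0.615 with an estimated correlation). The receptor gene Pdgfrb, a member of that list, was at -3.21 and Col5a1, at the highest value of the table in MEF replicate 2, at -2.06. Imprinted genes fell in 4 of 18, 6 over the list alone (camera adjusted p = 0.00112, adjusted p = 0.11 with an estimated correlation). Peg3 was at -2.42 and Mest at -2.59. The 1120 called genes, 789 higher and 331 lower, became 629 without OSK-D0 replicate 2, and with only the MEF and OSK-D0 libraries in the limma fit 0 passed (2499 at unadjusted p under 0.05).

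From day 0 to day 1, Nefl, a neurofilament gene, rose by 5.55 (SE 0.77, adjusted p = 0.000308), with 2150 (SD 227) against 49.5 (SD 30.4). Avil, an actin-regulating protein, rose by 4.84 (SE 0.70, adjusted p = 0.000451) and the natriuretic peptide gene Nppc by 4.92 (SE 0.75, adjusted p = 0.000514). Prrx2, a mesenchymal homeobox gene, fell by 5.52 (SE 0.78, adjusted p = 0.000293), the retrotransposon-derived Rtl3 fell by 7.03 (SE 0.72, adjusted p = 2.28e-05), Atoh8 fell by 5.00 (SE 0.63, adjusted p = 0.000118) and Fgfr3 fell by 4.93 (SE 0.69, adjusted p = 0.000293). Nog, a BMP antagonist, was listed at 0 at day 1 and at 49 (SD 25.5) at day 0. Contractile genes fell in 10 of 13, 11 over the list alone (camera adjusted p = 9.21e-15, adjusted p = 0.055 with an estimated correlation). Csrp1 was at -2.56, Tpm1 at -2.12 and Cnn1 at -4.26. Cholesterol synthesis genes rose in 4 of 18, 4 over the list alone (camera adjusted p = 4.66e-09, adjusted p = 0.057 with an estimated correlation). Msmo1 rose by 1.10. Jun differed by -0.88 (SE 0.37, adjusted p = 0.169) and Sap30 by -0.08 (SE 0.32, adjusted p = 0.962), neither of them called, and both Pou5f1 libraries stood at the highest value of the table, 21544. The 1010 called genes, 510 higher and 500 lower, became 568 without OSK-D0 replicate 1, 603 without OSK-D0 replicate 2, 396 without OSK-D1 replicate 2 and 53 with spread estimated from the compared libraries alone.

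By day 3, interferon-induced genes had risen and contractile genes had fallen against day 0. Trh, the thyrotropin-releasing hormone gene, rose by 10.57 (SE 0.79, adjusted p = 1.27e-07), with 4943 (SD 1660) against 2.5 (SD 2.12). Oas2, an antiviral synthetase, rose by 9.59 (SE 0.24, adjusted p = 2.18e-14), and the interferon-induced GTPases Igtp by 9.11 (SE 1.04, adjusted p = 9.47e-06), Gbp2 by 8.77 (SE 1.04, adjusted p = 1.32e-05) and Gbp3 by 8.32 (SE 0.64, adjusted p = 1.27e-07). Tagln, a smooth-muscle actin binder, fell by 7.69 (SE 0.64, adjusted p = 3.08e-07), with 19.5 (SD 4.95) against 4191 (SD 594), the myosin light chain Myl9 fell by 8.19 (SE 0.76, adjusted p = 7.55e-07), Prrx2 fell by 8.03 (SE 0.78, adjusted p = 1.08e-06) and the proteoglycan Fmod fell by 7.53 (SE 0.69, adjusted p = 5.68e-07). The interferon list rose in 18 of 19, 18 over the list alone (camera adjusted p = 1.47e-21, adjusted p = 0.00901 with an estimated correlation). Ifit1 rose by 7.80 and Stat2 by 5.17. Contractile genes fell in 12 of 13, 12 over the list alone (camera adjusted p = 1.24e-15, adjusted p = 0.0505 with an estimated correlation). Csrp1 was at -2.99. Epithelial genes rose in 10 of 21 and fell in 2, 10 and 2 over the list alone (camera adjusted p = 0.000143, adjusted p = 0.243 with an estimated correlation). The adhesion molecule Epcam rose by 4.40 and the tight-junction Ocln by 3.82. Pluripotency genes rose in 9 of 28, 10 over the list alone (camera adjusted p = 0.0183, adjusted p = 0.246 with an estimated correlation). Tfcp2l1 rose by 7.05 and L1td1 by 2.50. In total 2766 genes were called, 1372 higher and 1394 lower, and a medium change between day 0 and the later days may share in these differences.

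At day 5, Trh was higher than at day 0 by 10.16 (SE 0.79, adjusted p = 1.98e-07), Oas2 by 9.32 (SE 0.24, adjusted p = 3.54e-14) and Tdh by 9.03 (SE 0.61, adjusted p = 2.93e-08). Tfcp2l1 rose by 8.02 (SE 0.95, adjusted p = 1.16e-05), with a wide spread of 1728 (SD 1396), while Tagln fell by 7.54 (SE 0.64, adjusted p = 3.5e-07) and Acta2, at the highest value of the table at day 0, fell by 7.13 (SE 0.86, adjusted p = 1.4e-05). Epithelial genes rose in 17 of 21 and fell in 1, 19 and 1 over the list alone (camera adjusted p = 3.57e-09, adjusted p = 0.0808 with an estimated correlation). Epcam rose by 5.88 and Spint1 by 4.97. The interferon list rose in 17 of 19, 18 over the list alone (camera adjusted p = 4.81e-18, adjusted p = 0.0133 with an estimated correlation). Oas1a rose by 5.63. Pluripotency genes rose in 11 of 28 and fell in 1, 12 and 1 over the list alone (camera adjusted p = 0.00024, adjusted p = 0.0823 with an estimated correlation). Gdf3 rose by 6.64. The replicates stood apart in the delivered factors, with Pou5f1 at 656 and 21544, Sox2 at 1792 and 6116 and Klf4 at 3263 and 11663. Sap30 rose by 1.01 (SE 0.32, adjusted p = 0.0255), a call lost without OSK-D0 replicate 1 (0.94), OSK-D0 replicate 2 (1.09) or OSK-D5 replicate 2 (0.77). In total 3152 genes were called, 1571 higher and 1581 lower, and 1667 with spread estimated from the compared libraries alone.

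By day 7 of OSK, pluripotency and epithelial genes had risen. Trh was higher than at day 0 by 10.75 (SE 0.79, adjusted p = 6.53e-08), Dmgdh, an enzyme of choline breakdown, by 9.03 (SE 0.54, adjusted p = 7.15e-09) and Tdh by 8.78 (SE 0.61, adjusted p = 2.28e-08), and Gpx2, Cd74 and Sez6 were listed at 0 at day 0. Tagln fell by 9.15 (SE 0.64, adjusted p = 3.69e-08), with 6.5 (SD 2.12) against 4191 (SD 594), the activin subunit gene Inhba fell by 8.06 (SE 0.57, adjusted p = 2.81e-08) and the elastic-fibre gene Fbln5 fell by 7.88 (SE 0.61, adjusted p = 9.83e-08). Sap30 rose by 1.95 (SE 0.32, adjusted p = 0.00014), with 340 (SD 54.4) against 86.5 (SD 6.36), and Jun did not change, at 0.06 (SE 0.37, adjusted p = 0.95). Pluripotency genes rose in 19 of 28 and fell in 1, 19 and 1 over the list alone (camera adjusted p = 4.44e-08, adjusted p = 0.0267 with an estimated correlation). L1td1 rose by 2.70 and Gdf3 by 6.50. Epithelial genes rose in 20 of 21, 20 over the list alone (camera adjusted p = 1.01e-13, adjusted p = 0.0391 with an estimated correlation). Epcam rose by 8.32 and the protease inhibitor Spint1 by 6.73. The interferon list rose in 18 of 19, 18 over the list alone (camera adjusted p = 1.17e-13, adjusted p = 0.0267 with an estimated correlation). In total 3819 genes were called, 1806 higher and 2013 lower.

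Mesenchymal genes fell by day 7 in 18 of 23, 18 over the list alone (camera adjusted p = 5.83e-09, adjusted p = 0.148 with an estimated correlation). Cdh11 was at -4.86, the osteoblast regulator Runx2 at -4.62 and the repressor Zeb1 at -1.53. Extracellular matrix genes fell in 20 of 25, 21 over the list alone (camera adjusted p = 1.62e-11, adjusted p = 0.21 with an estimated correlation). Col5a1 was at -4.82 and Loxl1 at -6.68. Contractile genes fell in 13 of 13, 13 over the list alone (camera adjusted p = 1.13e-13, adjusted p = 0.0574 with an estimated correlation). Tpm1 was at -3.91. Glycolytic genes rose in 11 of 15, 11 over the list alone (camera adjusted p = 4.73e-06, adjusted p = 0.194 with an estimated correlation). Pkm, at the highest value of the table in both day 7 libraries, rose by 2.04 and the glucose transporter Slc2a1 by 2.51. Polycomb and DNA methylation genes rose in 8 of 14, 8 rose and 1 fell over the list alone (camera adjusted p = 0.000493, adjusted p = 0.175 with an estimated correlation). Jarid2 rose by 3.34 and Suz12 by 1.97. Imprinted genes fell in 9 of 18 and rose in 2, 10 and 2 over the list alone (camera adjusted p = 0.000264, adjusted p = 0.0775 with an estimated correlation). Dlk1 was at -5.10. Of the 1526 genes high in MEF 821 fell and 59 rose (camera adjusted p = 0.0267 with an estimated correlation), and of the 1266 genes high in ESC 472 rose and 16 fell (camera adjusted p = 0.0143 with an estimated correlation). Both sets were chosen on the MEF and ESC libraries and not on the OSK libraries compared here, though all libraries shared 1 fit.

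Between day 3 and day 7 of OSK, epithelial and pluripotency genes rose. Nanog, a core pluripotency factor, rose by 5.86 (SE 0.83, adjusted p = 0.000569), with 145 (SD 48.1) against 1.5 (SD 0.707), and Esrrb was listed at 0 at day 3 and at 61.5 (SD 2.12) at day 7. Ndufa4l2, a hypoxia-induced mitochondrial protein, rose by 7.82 (SE 1.09, adjusted p = 0.000517), Igfbp2 by 6.92 (SE 0.86, adjusted p = 0.000365), the homocysteine methyltransferase Bhmt by 6.39 (SE 0.64, adjusted p = 7.84e-05) and Cyp2b23 by 5.70 (SE 0.52, adjusted p = 5.43e-05). The tight-junction gene Cldn4 rose by 6.38 (SE 0.81, adjusted p = 0.000328) and the amino-acid transporter gene Slc6a17 fell by 3.94 (SE 0.55, adjusted p = 0.000517). Epithelial genes rose in 16 of 21, 19 over the list alone (camera adjusted p = 9.12e-14, adjusted p = 0.0391 with an estimated correlation). Esrp1 rose by 4.75. Pluripotency genes rose in 11 of 28, 14 over the list alone (camera adjusted p = 9.76e-07, adjusted p = 0.0364 with an estimated correlation). Dppa5a rose by 5.25. Glycolytic genes rose in 9 of 15, 9 over the list alone (camera adjusted p = 4.84e-10, adjusted p = 0.0767 with an estimated correlation). Ldha rose by 1.69 and Pdk1 by 2.65. Sap30 rose by 1.56 (SE 0.32, adjusted p = 0.00572), a call lost without OSK-D3 replicate 1 (1.26) or OSK-D7 replicate 2 (1.39). The 1216 called genes, 541 higher and 675 lower, became 273 without OSK-D3 replicate 1 and 287 without OSK-D7 replicate 2. With the 4 compared libraries alone in the limma fit 0 passed, and 3700 had an unadjusted p under 0.05.

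OSK day 7 differed from ESC in pluripotency, Hox, interferon and germline genes. Avil was higher at day 7 by 10.02 (SE 0.70, adjusted p = 1.23e-08), the desmosomal Pkp1 by 9.60 (SE 0.50, adjusted p = 1.82e-10), the skeletal myosins Myh1 by 9.56 (SE 0.95, adjusted p = 6.03e-07) and Myh2 by 9.53 (SE 0.44, adjusted p = 5.08e-11), and the kinesin Kif1a by 9.51 (SE 0.35, adjusted p = 4.46e-12). Jun was higher by 5.18 (SE 0.37, adjusted p = 7.39e-09), Klf4, at the highest value of the table in OSK-D7 replicate 1, by 3.78 (SE 0.50, adjusted p = 1.05e-05) and Myc by 3.80 (SE 0.83, adjusted p = 0.00134), and Sap30 did not differ, at 0.01 (SE 0.32, adjusted p = 1). Tuba3a, a testis tubulin, was lower by 8.59 (SE 0.69, adjusted p = 2.97e-08), and the germline genes Dazl and Hormad1 and the cofactor Tcl1 were listed at 0 at day 7. Pluripotency genes were lower in 25 of 28, 26 over the list alone (camera adjusted p = 1.61e-12, adjusted p = 0.00901 with an estimated correlation). Lefty2 was at -7.60, Tet1 at -6.12 and Tbx3 at -3.99. Hox genes were higher in 22 of 25, 23 over the list alone (camera adjusted p = 2.73e-11, adjusted p = 0.0267 with an estimated correlation). Hoxc6 was at 4.92. Interferon genes were higher in 19 of 19, 19 over the list alone (camera adjusted p = 8.73e-13, adjusted p = 0.0267 with an estimated correlation). Rtp4 was at 8.24. Germline genes were lower in 8 of 12, 8 over the list alone (camera adjusted p = 0.000509, adjusted p = 0.0345 with an estimated correlation). Stk31 was at -4.06. In total 5505 genes were called, 2930 higher and 2575 lower at day 7.

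Position between MEF (0 percent) and ESC (100 percent) was followed with the 1526 genes high in MEF and the 1266 high in ESC. For the MEF-high genes OSK moved from 7.99 percent (SD 2.28) at day 0 to 23.6 (SD 4.22) at day 1, 34.9 (SD 2.85) at day 3, 37.1 (SD 4.76) at day 5 and 46.3 (SD 5.21) at day 7. For the ESC-high genes the same course gave 13.3 percent (SD 2.41), 19.6 (SD 0.0684), 30.9 (SD 2.29), 38.9 (SD 1.77) and 46.2 (SD 0.471). OSK+cJun reached 33.6 percent (SD 4.34) and 28.5 percent (SD 0.078) at day 7, OSK+shSap30 39.3 percent (SD 1.19) and 39.9 percent (SD 0.142), and iPSC 62.6 percent (SD 7.3) and 83.6 percent (SD 4.17), MEF-high before ESC-high in each pair. Positions average log2 values, so a low remainder of a fibroblast transcript counts strongly. In iPSC 340 abundant MEF-high genes kept a median of 6.9 percent of the MEF value, with the ESC value subtracted. In replicates 1 and 2 at day 7 the MEF-high position was 42.7 and 50 percent in OSK and 30.6 and 36.7 percent in OSK+cJun, and replicate 2 stood above replicate 1 in each of the 9 groups of both courses, so the SDs hold a difference between replicate numbers, which the labels do not pair. At day 0 OSK+cJun stood at 8.65 percent (SD 2.28) for MEF-high and 11.7 percent (SD 0.345) for ESC-high genes. With the median over genes in place of the mean, OSK day 0 stood at 5.33 percent for MEF-high and 2.43 percent for ESC-high genes, and OSK+cJun day 7 at 18.7 percent for ESC-high genes.

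**Figure D3:**
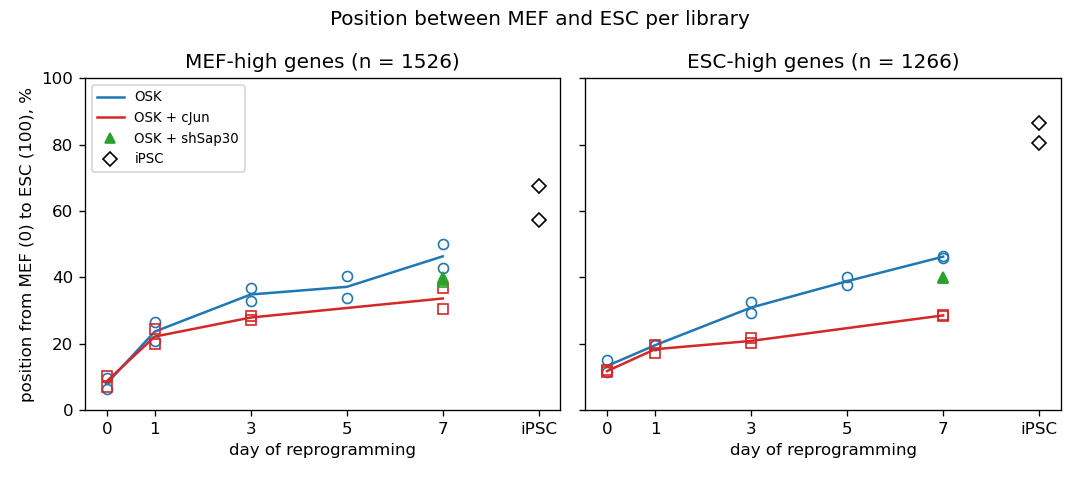
Position of each library between MEF (0 percent) and ESC (100 percent) by day, for 1526 genes high in MEF and 1266 genes high in ESC. Open points are libraries, n = 2 per group, with iPSC at the right. Lines join group means, and the filled triangle is the mean of OSK+shSap30.

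Some genes turned back within the OSK course, with 168 higher at day 3 than at day 0 and then lower at day 7, and 79 lower and then higher. Genes moving in 1 direction through both steps numbered 79 upward and 116 downward. Both steps share the day 3 libraries with opposite sign, so part of the genes that turned back may come from these. With OSK-D3 replicate 1 for the first step and replicate 2 for the second, 37 and 23 genes turned back, and 87 and 28 the other way round. They were 39 and 21 without OSK-D3 replicate 1, 127 and 48 without OSK-D0 replicate 1, 39 and 25 without OSK-D7 replicate 2, and 0 with spread estimated from the compared libraries alone.

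At day 0, Jun was higher with added Jun by 2.71 (SE 0.37, adjusted p = 0.00345), with 4820 (SD 288) against 748 (SD 180). Serinc5, a membrane protein that restricts retroviruses, was higher by 2.08 (SE 0.27, adjusted p = 0.00234), and Lrp4, a receptor at the neuromuscular junction, was lower by 3.12 (SE 0.49, adjusted p = 0.0194). Pou5f1 differed by -0.49 (SE 0.97, adjusted p = 1), Sox2 by -0.38 (SE 0.48, adjusted p = 1), Klf4 by -0.61 (SE 0.50, adjusted p = 1) and Sap30 by 0.07 (SE 0.32, adjusted p = 1), all short of the call. For Pou5f1, Sox2 and Klf4 the pooled SEs were widened by the gap between the OSK day 5 replicates. In total 12 of 16038 genes were called with limma, 5 higher and 7 lower, while 712 had an unadjusted p under 0.05, and no member of any list was called. A stricter low-value filter left 7 called genes, and a replicate block within the 8 course groups, chosen after the results were seen, gave 21. The Jun call was lost without OSK-D0 replicate 2 (2.46) or OSK-cJun-D0 replicate 2 (2.65), the latter of which left 1 called gene and ended the Serinc5 call (2.07), and Lrp4 was lost without OSK-D0 replicate 2 (-2.09), OSK-cJun-D0 replicate 1 (-3.02) or OSK-cJun-D0 replicate 2 (-3.22). With the 4 compared libraries alone 0 passed (984 at unadjusted p under 0.05).

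At day 1, Jun was higher with added Jun by 4.03 (SE 0.37, adjusted p = 4.93e-05), with 6526 (SD 570) against 404 (SD 90.5). Srpx2, a secreted angiogenic factor, was higher by 4.26 (SE 0.46, adjusted p = 0.000183), with 295 (SD 4.24) against 14.5 (SD 2.12), the epidermal Slurp1 by 4.66 (SE 0.58, adjusted p = 0.000851) and the apoptosis inhibitor Birc7 by 3.98 (SE 0.57, adjusted p = 0.0016). Trh was listed at 0 with added Jun and at 59.5 (SD 48.8) without. Keratinocyte genes rose in 3 of 13, 4 over the list alone (camera adjusted p = 1.7e-06, adjusted p = 0.069 with an estimated correlation). Sfn was at 3.23, Krt6a at 3.41 and Krt13 at 2.19. Sap30 differed by -0.70 (SE 0.32, adjusted p = 0.381), short of the call. The 318 called genes, 199 higher and 119 lower, became 160 without OSK-D1 replicate 1, 52 without OSK-D1 replicate 2, 69 without OSK-cJun-D1 replicate 1 and 119 without OSK-cJun-D1 replicate 2. Krt6a (3.23 to 3.58) and Krt13 (2.13 to 2.25) were not called with any 1 of these 4 libraries left out, nor Sfn without OSK-D1 replicate 2 (2.67) or OSK-cJun-D1 replicate 1 (2.97). With the 4 compared libraries alone 0 passed (2161 at unadjusted p under 0.05).

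At day 3, Jun was higher with added Jun by 3.94 (SE 0.37, adjusted p = 6.44e-06). Ngef, a guanine-nucleotide exchange factor of neurons, was higher by 6.04 (SE 0.76, adjusted p = 7e-05), with 519 (SD 238) against 6.5 (SD 0.707), the parathyroid-hormone-related Pthlh by 5.35 (SE 0.59, adjusted p = 2.45e-05), Srpx2 by 5.31 (SE 0.46, adjusted p = 3.81e-06) and the serine protease gene Tmprss11b by 5.23 (SE 0.55, adjusted p = 2.07e-05). Trh was lower by 7.40 (SE 0.79, adjusted p = 2.5e-05), with 27.5 (SD 0.707) against 4943 (SD 1660), Dmrtc2 fell by 6.75 (SE 0.81, adjusted p = 4.6e-05), Nr0b1, a nuclear receptor of naive pluripotency, fell by 6.07 (SE 0.72, adjusted p = 4.39e-05), and Tdh was lower, with an adjusted p = 2.45e-05 and 8.5 (SD 4.95) against 401 (SD 61.5). Pluripotency genes were lower in 11 of 28, 11 over the list alone (camera adjusted p = 7.23e-05, adjusted p = 0.062 with an estimated correlation). Zfp42 was at -4.50. Interferon genes were lower in 5 of 19, 6 over the list alone (camera adjusted p = 3.58e-07, adjusted p = 0.0808 with an estimated correlation). The antiviral Rsad2 was at -3.97 and Ddx58 at -2.19. Polycomb and DNA methylation genes were lower in 3 of 14, 5 over the list alone (camera adjusted p = 0.000649, adjusted p = 0.186 with an estimated correlation). The demethylating Tet2 was at -2.25. Sap30 differed by -0.89 (SE 0.32, adjusted p = 0.0921), short of the call. The 1210 called genes, 642 higher and 568 lower, became 759 without OSK-D3 replicate 1, 717 without OSK-D3 replicate 2 and 751 without OSK-cJun-D3 replicate 1.

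At day 7, Jun was higher with added Jun by 3.27 (SE 0.37, adjusted p = 2.1e-05) and Sap30 was lower by 2.01 (SE 0.32, adjusted p = 0.000353), with 83.5 (SD 13.4) against 340 (SD 54.4). Ngef was higher by 7.80 (SE 0.76, adjusted p = 5.12e-06), the adrenergic receptor Adra1d by 6.02 (SE 0.56, adjusted p = 3.77e-06), the peptide gene Calcb by 5.89 (SE 0.59, adjusted p = 6.81e-06), the neurotrophin receptor Ntrk2 by 5.89 (SE 1.15, adjusted p = 0.0021) and the neuropeptide Y receptor Npy2r by 5.69 (SE 0.65, adjusted p = 2.19e-05), and Slitrk1 and Stk26 were listed at 0 without added Jun. Cyp2b23 was lower by 5.70 (SE 0.52, adjusted p = 3.77e-06), Bhmt fell by 5.62 (SE 0.64, adjusted p = 2.2e-05), the glutamate receptor subunit Grin1 fell by 5.12 (SE 0.66, adjusted p = 6.14e-05), Tdh fell by 5.11 (SE 0.61, adjusted p = 3.27e-05) and the homeobox gene En2 fell by 4.95 (SE 0.80, adjusted p = 0.00043). Pluripotency genes were lower in 15 of 28, 17 over the list alone (camera adjusted p = 2.92e-08, adjusted p = 0.0267 with an estimated correlation). Nr0b1 was at -4.47 and Dppa5a at -4.46. Mesenchymal genes were higher in 8 of 23 and lower in 2, 9 and 2 over the list alone (camera adjusted p = 0.000312, adjusted p = 0.387 with an estimated correlation). Runx2 was at 4.33 and S100a4 at 4.99. Keratinocyte genes were higher in 4 of 13, 6 over the list alone (camera adjusted p = 0.00123, adjusted p = 0.204 with an estimated correlation). Krt6a was at 4.60 and Krt13 at 3.90. The 1891 called genes, 1084 higher and 807 lower, became 1128 without OSK-D7 replicate 2, 1046 without OSK-cJun-D7 replicate 1 and 541 with spread estimated from the compared libraries alone.

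Epithelial genes at day 7 were lower with added Jun in 7 of 21 and higher in 1, 12 and 2 over the list alone (camera adjusted p = 0.0334, adjusted p = 0.575 with an estimated correlation). The desmosomal Dsp was at 2.67. Spint1 was among the lower genes at -3.33 (SE 0.58, adjusted p = 0.000814), a call lost with 0.1 in place of 1 added to the values (-3.36). Genes of the p53 and senescence list were lower in 4 of 18 and higher in 1, 4 and 1 over the list alone (camera adjusted p = 0.013, adjusted p = 0.462 with an estimated correlation). The apoptosis gene Pmaip1 was at -2.11 and Perp at 2.87. Interferon genes did not differ at day 7, with 0 called higher of 19, 0 over the list alone (camera adjusted p = 0.832, adjusted p = 0.95 with an estimated correlation). Of the genes high in MEF 323 were higher and 43 lower (camera adjusted p = 2.58e-09, adjusted p = 0.2 with an estimated correlation), and of those high in ESC 31 were higher and 239 lower (camera adjusted p = 4.44e-07, adjusted p = 0.055 with an estimated correlation). These sets were chosen on the MEF and ESC libraries, which are not compared here but shared the same fit.

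The change from day 0 to day 7 differed between OSK+cJun and OSK in 613 genes, 395 toward higher and 218 toward lower values with added Jun. Gpr50, an orphan receptor related to the melatonin receptors, differed by 6.79 (SE 0.82, adjusted p = 0.000435), Tmprss11b by 6.10 (SE 0.78, adjusted p = 0.000607), Adra1d by 5.95 (SE 0.80, adjusted p = 0.00067), Ngef by 5.99 (SE 1.07, adjusted p = 0.00525) and Npy2r by 5.69 (SE 0.92, adjusted p = 0.00259). Bhmt differed by -5.62 (SE 0.91, adjusted p = 0.00259), while Cyp2b23 was listed at 0 at day 0 of both courses and reached 185 (SD 64.3) in OSK against 2.5 (SD 0.707) in OSK+cJun. Runx2 differed by 4.19 (SE 0.66, adjusted p = 0.00202) and the elastic-fibre gene Fbln5 by 4.60 (SE 0.86, adjusted p = 0.00764). Pluripotency genes differed downward in 4 of 28, 10 over the list alone (camera adjusted p = 3.27e-06, adjusted p = 0.0408 with an estimated correlation), and mesenchymal genes upward in 3 and downward in 1 of 23, 5 and 1 over the list alone (camera adjusted p = 0.000264, adjusted p = 0.38 with an estimated correlation). Sap30 differed by -2.08 (SE 0.45, adjusted p = 0.0147), a call lost without OSK-D0 replicate 1 (-2.01), OSK-D7 replicate 2 (-1.92), OSK-cJun-D0 replicate 2 (-1.85) or OSK-cJun-D7 replicate 1 (-1.92). The count became 324 without OSK-D0 replicate 1, 379 without OSK-D0 replicate 2, 211 without OSK-D7 replicate 2, 269 without OSK-cJun-D0 replicate 1, 335 without OSK-cJun-D0 replicate 2, 208 without OSK-cJun-D7 replicate 1 and 331 with spread estimated from the compared libraries alone. It became 930 with a replicate block within the 8 course groups, chosen after the results were seen.

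Within OSK+cJun from day 0 to day 7, Aldh3a1, an aldehyde dehydrogenase of epithelia, rose by 9.96 (SE 0.74, adjusted p = 1.07e-07), a fold that may be understated as day 7 stood at the highest value of the table. Avil rose by 9.55 (SE 0.70, adjusted p = 9.57e-08), the keratin gene Krt8 by 8.66 (SE 0.91, adjusted p = 3.35e-06) and the immunoproteasome gene Psmb8 by 8.38 (SE 1.10, adjusted p = 3.23e-05). Tagln fell by 8.60 (SE 0.64, adjusted p = 8.74e-08), Igfbp7 fell by 8.39 (SE 0.54, adjusted p = 1.59e-08), Myl9 fell by 8.15 (SE 0.76, adjusted p = 7.16e-07), Lox fell by 7.78 (SE 0.91, adjusted p = 9.65e-06) and Acta2, at the highest value of the table at day 0, fell by 7.68 (SE 0.86, adjusted p = 6.49e-06). Sap30 did not change, at -0.13 (SE 0.32, adjusted p = 0.852). The interferon list rose in 17 of 19, 17 over the list alone (camera adjusted p = 1.88e-19, adjusted p = 0.0107 with an estimated correlation). Irf7 rose by 6.01. Epithelial genes rose in 17 of 21, 18 over the list alone (camera adjusted p = 6.62e-13, adjusted p = 0.0435 with an estimated correlation). Epcam rose by 7.58 and Ocln by 5.17. Pluripotency genes rose in 8 of 28, 8 over the list alone (camera adjusted p = 0.00789, adjusted p = 0.204 with an estimated correlation). Sall4 rose by 3.55 and Zfp42 by 2.66. Keratinocyte genes rose in 7 of 13, 10 over the list alone (camera adjusted p = 2.41e-05, adjusted p = 0.106 with an estimated correlation). Krt13 rose by 4.99 and Krt6a by 5.22. In total 2836 genes were called, 1426 higher and 1410 lower.

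The hairpin against Sap30 at day 7 went with a fall of Sap30 to 30.5 (SD 14.8) from 340 (SD 54.4). Lrrc15, a membrane protein of stroma, was higher by 4.68 (SE 0.43, adjusted p = 1.33e-05), with 81.5 (SD 20.5) against 2.5 (SD 2.12), the BMP ligand Bmp8b by 4.97 (SE 0.70, adjusted p = 0.000289), the serine protease Htra3 by 4.31 (SE 0.55, adjusted p = 0.000168) and the fatty-acid binder Fabp3 by 4.11 (SE 0.58, adjusted p = 0.000291). H2-DMb1, which loads class II peptides, was listed at 0 with the hairpin and at 49.5 (SD 19.1) without it. Psmb8 was lower by 4.86 (SE 1.10, adjusted p = 0.00836), a call lost without OSK-D7 replicate 2 (-4.58) or OSK-shSap30 replicate 2 (-3.52) and with 0.1 in place of 1 added (-4.91). Interferon genes were lower in 5 of 19, 6 over the list alone (camera adjusted p = 0.000579, adjusted p = 0.232 with an estimated correlation). Stat2 was at -2.46 and Ifit3 at -3.43. Imprinted genes were higher in 7 of 18 and lower in 3, 10 and 3 over the list alone (camera adjusted p = 0.0011, adjusted p = 0.11 with an estimated correlation). Igf2r was at 1.90, Plagl1 at 3.13 and Zim1 at 3.44. Genes of the p53 and senescence list were higher in 4 of 18, 4 over the list alone (camera adjusted p = 0.000593, adjusted p = 0.258 with an estimated correlation). Ccng1, at the highest value of the table in OSK-shSap30 replicate 2, was at 2.61 and Perp at 2.72. The 1580 called genes, 791 higher and 789 lower, became 512 without OSK-D7 replicate 2 and 929 without OSK-shSap30 replicate 2. With the 4 compared libraries alone 0 passed (3276 at unadjusted p under 0.05), and no control hairpin was in the series.

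Pluripotency genes were lower with the hairpin in 5 of 28 and higher in 1, Lin28a, 5 and 1 over the list alone (camera adjusted p = 0.01, adjusted p = 0.214 with an estimated correlation). Dppa4 was among the lower genes and was listed at 0 with the hairpin. Primitive endoderm genes were higher in 3 of 9 and lower in 1, 4 and 1 over the list alone (camera adjusted p = 0.0205, adjusted p = 0.38 with an estimated correlation). The basement-membrane gene Lamb1 was at 2.41 and Col4a1 at 1.83. Of the other members of the Sin3 complex 0 of 17 were called, 0 over the list alone (camera adjusted p = 0.631, adjusted p = 0.771 with an estimated correlation). The deacetylase Hdac1 was at -0.93 (SE 0.17, adjusted p = 0.00158), below the fold threshold. Jun differed by -0.43 (SE 0.37, adjusted p = 0.476), Pou5f1 by -0.11 (SE 0.97, adjusted p = 0.984), Sox2 by -0.63 (SE 0.48, adjusted p = 0.417) and Klf4, at the highest value of the table in OSK-D7 replicate 1, by -1.05 (SE 0.50, adjusted p = 0.169), all short of the call. The gap between the OSK day 5 replicates widened the pooled SEs of Pou5f1, Sox2 and Klf4, so a change in these factors may have been missed.

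Compared with OSK+cJun at day 7, the hairpin libraries differed in Jun by -3.71 (SE 0.37, adjusted p = 7.2e-06), Srpx2 by -6.27 (SE 0.46, adjusted p = 4.91e-07), Ntrk2 by -6.88 (SE 1.15, adjusted p = 0.000588), the exchange factor gene Dock8 by -6.85 (SE 0.70, adjusted p = 8.24e-06) and Gbp2 by -6.12 (SE 1.04, adjusted p = 0.000688). Bmp8b was higher by 5.76 (SE 0.70, adjusted p = 3.24e-05) and the cytokine receptor Cntfr by 5.83 (SE 0.79, adjusted p = 9.6e-05), and the caudal homeobox gene Cdx1 was listed at 0 with added Jun. Sap30 was lower, with an adjusted p = 0.00307 and 30.5 (SD 14.8) against 83.5 (SD 13.4), a call lost without OSK-shSap30 replicate 1, where the fold lay just short of the threshold. Genes of the p53 and senescence list were higher in 8 of 18, 8 over the list alone (camera adjusted p = 2.52e-07, adjusted p = 0.105 with an estimated correlation). Bbc3 was at 3.23 and Ccng1, with its value in OSK-shSap30 replicate 2 at the highest of the table, at 2.92. Pluripotency genes were higher in 8 of 28 and lower in 1, 9 and 1 over the list alone (camera adjusted p = 0.00243, adjusted p = 0.148 with an estimated correlation). Nr0b1 was at 4.09 and Nr5a2 at 4.36. The 2266 called genes, 1108 higher and 1158 lower, became 1459 without OSK-cJun-D7 replicate 1 and 522 with spread estimated from the compared libraries alone.

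The effects of added Jun and of the hairpin at day 7 were compared over 16038 genes. Higher in both were 307 genes, lower in both 147, higher with Jun and lower with the hairpin 19, and the reverse 21, against 53.5, 39.7, 53.3 and 39.8 for independent lists (n1×n2/N). In 20 simulations with the same OSK day 7 libraries in both comparisons, 0 genes were called in both in any of the 4 ways, a value that leaves out the effects of both and so sets no expected count for them. The correlation of the folds was 0.409, against 0.5 in the simulations, and 0.55 without OSK-D7 replicate 1 and 0.439 without replicate 2, against 0.669 simulated with 1 shared library. Their covariance was 0.491, against 0.202 simulated with the fitted spread and 0.22 with the OSK-D7 spread, differences of 0.289 and 0.271, and the difference was 0.459 without OSK-D7 replicate 1 and 0.146 without replicate 2. These differences estimate what the comparisons share beyond spread between libraries, which includes any offset of the OSK day 7 group itself. The simulations took libraries as independent, while replicate differences of OSK and OSK+cJun at day 7 correlated by 0.306. That would lower the simulated correlation and covariance, by an amount that was not tested. Part of the excess over independent lists may come from the shared controls, so the OSK day 7 libraries were also split between the comparisons, 1 each, a check chosen after the results were seen. With replicate 1 for added Jun and replicate 2 for the hairpin, the correlation was 0.19 and the covariance 0.27. The other way round these were 0.195 and 0.272. In both splits more genes were called in the same direction than for independent lists. Genes lower with Jun and higher with the hairpin were not fewer than for independent lists in the first split, though they were in the second.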

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

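The alternatives without a variance trend (492 genes), with spread estimated without OSK-D5 replicate 1 (735) and with a replicate block within the 8 course groups (930) were added for the count in this part after the results were seen. The change from day 0 to day 7 differed between OSK+cJun and OSK in 613 genes, and these were marked because the effect of time depended on added Jun (n = 2 libraries in each of 4 groups). Slitrk1, a synaptic adhesion protein, differed by 7.38 (SE 1.38, adjusted p = 0.00693), and it was listed at 0 in OSK day 7 and at 66 (SD 9.9) in OSK+cJun day 7. Gpr50, an orphan receptor, differed by 6.79 (SE 0.82, adjusted p = 0.000435), with 1545 (SD 504) in OSK+cJun day 7 against 63.5 (SD 43.1) in OSK day 7. The protease gene Tmprss11b differed by 6.10 (SE 0.78, adjusted p = 0.000607), the exchange factor gene Ngef by 5.99 (SE 1.07, adjusted p = 0.00525) and the adrenergic receptor gene Adra1d by 5.95 (SE 0.80, adjusted p = 0.00067). Stk26, a kinase of cell polarity, differed by 5.79 (SE 1.18, adjusted p = 0.0107) and was listed at 0 in OSK day 7, the oxysterol-binding Osbp2 by 5.76 (SE 1.08, adjusted p = 0.00701) and the neuropeptide receptor Npy2r by 5.69 (SE 0.92, adjusted p = 0.00259).

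In the other direction, Cyp2b23, a cytochrome of liver, differed by -5.70 (SE 0.74, adjusted p = 0.000588) and Bhmt, a homocysteine methyltransferase, by -5.62 (SE 0.91, adjusted p = 0.00259). Clec2i, a lectin, differed by -5.73 (SE 1.19, adjusted p = 0.0112), the myosin light chain Mylpf by -5.16 (SE 1.37, adjusted p = 0.044), the pyrimidine-breakdown enzyme Upb1 by -5.00 (SE 1.34, adjusted p = 0.0442), the glutathione peroxidase Gpx2 by -4.98 (SE 1.03, adjusted p = 0.0111), the cytochrome Cyp2c70 by -4.97 (SE 1.16, adjusted p = 0.0217) and Dppa5a, a protein of pluripotent cells, by -4.96 (adjusted p = 0.00964). Sap30 differed by -2.08 (SE 0.45, adjusted p = 0.0147). The calls of Slitrk1, Gpr50, Tmprss11b, Ngef, Adra1d, Stk26, Osbp2, Npy2r, Cyp2b23 and Bhmt held with any 1 of the 8 compared libraries left out. Without OSK-D7 replicate 2 the calls of Clec2i (-5.73), Gpx2 (-4.13), Cyp2c70 (-4.64) and Dppa5a (-4.73) were lost. Clec2i (-4.94) and Gpx2 (-4.71) were also lost without OSK-cJun-D7 replicate 1, Clec2i without OSK-cJun-D0 replicate 2 (-4.94) and Cyp2c70 without OSK-cJun-D7 replicate 2 (-3.68) or any 1 of the 4 day 0 libraries (-4.97). Mylpf was lost with any 1 of the 8 libraries left out (-5.66 to -4.66), and Upb1 with 6 of them, among them OSK-D7 replicate 1 (-5.20). Sap30 was lost without OSK-D0 replicate 1 (-2.01), OSK-D7 replicate 2 (-1.92), OSK-cJun-D0 replicate 2 (-1.85) or OSK-cJun-D7 replicate 1 (-1.92), and the count of 613 became 208 without OSK-cJun-D7 replicate 1.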

How the results depend on the processing

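The tests without a variance trend, with spread estimated without OSK-D5 replicate 1, with a replicate block within the 8 course groups, with the OSK-D7 libraries split between the Jun and hairpin comparisons and those of the genes that turned back within the OSK course were chosen after the results were seen, and the others before. With 2 libraries per group the results rest on spread pooled over all groups, and every effect of medium, passage, strain or batch that follows a group is part of that group's difference. Depth is unknown and the values were forced to a common distribution, so a change in total RNA cannot be seen and genes at the shared highest value of 21544 are capped. The alternatives needing counts (the DESeq2 test, RLE scaling and upper-quartile scaling) were not run. Of 1364 named-gene results, called or not, 115 lost their call with 0.1 in place of 1 added to the values, 11 without a low-value filter, 3 of 1333 with a stricter filter, 48 without a variance trend and 486 (5 gained) with spread from the compared groups alone. Reversals numbered 0 under any alternative, but a change of sign was counted only for genes called in the main fit or in the alternative. Genes called in neither may have changed sign. Of 5636 named-gene results with 1 library left out, called or not with all libraries, 1024 lost their call and 5 gained one, and of 1273 with spread estimated without OSK-D5 replicate 1, 8 lost it and 5 gained one. Of 512 list tests, 159 lost their call with an estimated correlation, which left 25 of 184 called, and with fry in place of camera 33 were lost and 43 gained.

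With spread estimated from only the compared groups the counts fell. Fewer libraries inform the spread there, but the drops were unequal at the same number of libraries. OSK day 3 against day 0 gave 2466 genes, against 2766 with all libraries, while other comparisons fell to 0. Whether the pooled spread was too small for some groups was not tested. The counts were 376 for iPSC against ESC, 53 for OSK day 1, 1667 for OSK day 5, 541 for added Jun at day 7, 331 for the interaction and 522 for the hairpin against added Jun. They were 0 in 5 comparisons, with 2499 genes at unadjusted p under 0.05 for OSK day 0 against MEF, 3700 for OSK day 7 against day 3, 984 and 2161 for added Jun at days 0 and 1, and 3276 for the hairpin against OSK day 7. With a stricter low-value filter, which tests fewer genes (14116), 7 genes passed for added Jun at day 0. Without the fold threshold 2373 passed for the hairpin against OSK day 7, by construction of a looser rule.

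Leaving out 1 library gave 6196 to 7005 genes for ESC against MEF, 5407 to 6560 for iPSC against MEF, 4727 to 5130 for OSK day 7 against ESC and 2206 to 2313 for OSK+cJun day 7 against its day 0, and for OSK 2045 to 2448 at day 3, 2399 to 3033 at day 5 and 2999 to 3556 at day 7 against day 0. It gave wider ranges of 536 to 872 for iPSC against ESC, 629 to 1349 for OSK day 0 against MEF, 396 to 724 for OSK day 1 and 273 to 1334 for OSK day 7 against day 3. For added Jun the ranges were 1 to 12 at day 0, 52 to 160 at day 1, 717 to 810 at day 3, 1046 to 1741 at day 7 and 208 to 645 for the interaction. The hairpin gave 512 to 1787 against OSK day 7 and 1459 to 2049 against added Jun, and the correlation of the Jun and hairpin effects ran from 0.364 to 0.55, the highest with 1 shared OSK-D7 library, for which 0.669 was simulated without effects, and it was 0.19 and 0.195 with the OSK-D7 libraries split between the comparisons. Genes higher at day 3 and then lower at day 7 of OSK numbered 39 to 176 and the reverse 21 to 67, against 168 and 79 with all libraries. They were 0 with only the compared groups, 37 and 23 with OSK-D3 replicate 1 for the first step and replicate 2 for the second, and 87 and 28 the other way round. Fewer libraries explain part of these drops by construction, and why single libraries differed was not tested.

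Positions moved with the rule for choosing or averaging genes, and the cause was not tested. With the median over genes, OSK day 0 stood at 5.33 (MEF-high) and 2.43 (ESC-high), OSK day 7 at 41.3 (ESC-high), OSK+cJun day 7 at 29.1 and 18.7, OSK+shSap30 at 35.3 and 35.1, and iPSC at 88.9 (ESC-high). With 0.1 added the ESC-high position was 16 for OSK day 0, 50.1 for OSK day 7, 31.2 for OSK+cJun day 7 and 42.5 for OSK+shSap30, whose MEF-high position was 36.6. With genes chosen at a log2 fold of 2 the ESC-high position was 46.9 for OSK day 7, 29 for OSK+cJun day 7 and 40.1 for OSK+shSap30, whose MEF-high position was 36.7.

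The replicates of different groups share only a number, and a replicate block was fitted as a check. It gave 14 genes for added Jun at day 0, 383 at day 1, 777 for the interaction, 1738 for the hairpin against OSK day 7 and 6965 for ESC against MEF, and 0 of 1364 named-gene results gained or lost a call. Differences between replicates correlated by 0.192 to 0.331 (mean 0.256, 28 pairs) among the 8 groups of the OSK and OSK+cJun courses other than OSK day 5, and by -0.079 to 0.033 between MEF and these groups, a hint from the data and not from the design. A block within those 8 groups gave 21 genes for added Jun at day 0 and 930 for the interaction, with 12 named-gene calls lost and 1 gained, and the cause was not tested.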

Other observations

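All tests of explanations in this part were chosen after the results were seen, except the test of a delay with the hairpin, whose prediction was written before. Lists little used in the report gave these values between ESC and MEF (n = 2 libraries per group). Proliferation genes rose in 20 and fell in 0 of 23, 20 and 0 over the list alone (camera adjusted p = 3.14e-06, adjusted p = 0.517 with an estimated correlation). The replication helicase gene Mcm5 rose by 2.68 (SE 0.27, adjusted p = 1.97e-07). Macrophage and blood genes rose in 1 and fell in 12 of 14, 1 and 12 over the list alone (camera adjusted p = 0.00845, adjusted p = 0.616 with an estimated correlation). Cx3cr1 and Adgre1, receptors of macrophages, were listed at 0 in ESC. Primitive endoderm genes rose in 1 and fell in 6 of 9, 1 and 6 over the list alone (camera adjusted p = 0.00106, adjusted p = 0.204 with an estimated correlation). The basement-membrane gene Col4a1 fell by 8.05 (SE 0.24, adjusted p = 2.07e-13). Inflammatory factors rose in 2 and fell in 14 of 17, 2 and 14 over the list alone (camera adjusted p = 0.000264, adjusted p = 0.262 with an estimated correlation). The macrophage growth factor gene Csf1 fell by 8.41 (SE 0.76, adjusted p = 1.06e-07).

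Other lists had called members between ESC and MEF without a call of the list. Primed pluripotency and mesendoderm genes rose in 7 and fell in 2 of 10, 8 and 2 over the list alone (camera adjusted p = 0.079, adjusted p = 0.241 with an estimated correlation). Otx2, a factor of primed pluripotency, was listed at 0 in MEF. Trophoblast genes rose in 7 and fell in 1 of 11, 7 and 2 over the list alone (camera adjusted p = 0.0875, adjusted p = 0.337 with an estimated correlation). Tfap2c, a trophoblast factor, rose by 7.97 (SE 0.71, adjusted p = 5.33e-08). Genes of the Sin3 complex rose in 5 and fell in 0 of 17, 5 and 0 over the list alone (camera adjusted p = 0.0748, adjusted p = 0.243 with an estimated correlation). The scaffold gene Sin3a rose by 1.53 (SE 0.22, adjusted p = 1.36e-05). Neural genes rose in 2 and fell in 6 of 14, 2 and 6 over the list alone (camera adjusted p = 0.388, adjusted p = 0.727 with an estimated correlation). Endothelial genes rose in 4 and fell in 2 of 9, 4 and 2 over the list alone (camera adjusted p = 0.804, adjusted p = 0.914 with an estimated correlation). Muscle genes rose in 2 and fell in 3 of 9, 2 and 3 over the list alone (camera adjusted p = 0.689, adjusted p = 0.926 with an estimated correlation). Oxidative phosphorylation genes rose in 2 and fell in 0 of 19, 0 and 0 over the list alone (camera adjusted p = 0.274, adjusted p = 0.883 with an estimated correlation). Genes of the two-cell stage rose in 3 and fell in 0 of 6, 2 and 0 over the list alone (camera adjusted p = 0.205, adjusted p = 0.586 with an estimated correlation).

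Sex-linked transcripts differed between libraries. Xist, which silences an X chromosome in female cells, stood at 26 and 31 in ESC, 174 and 309 in iPSC, 1615 and 3617 in MEF and 168 and 2154 in OSK day 5. The 4 Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were present in ESC and MEF alike, Ddx3y at 511 and 407 in ESC and 328 and 252 in MEF.

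The fibroblast transcripts in iPSC were weighed as mixed-in fibroblast RNA or as fibroblast genes still expressed by iPSC. Of 340 abundant genes high in MEF, 92.6 percent were higher in iPSC replicate 2 than in replicate 1, but these same genes had set replicate 2 apart, so the value did not decide on RNA of fibroblasts mixed in unequal amounts. With the ESC value subtracted from the iPSC and the MEF value, the median gene kept 6.9 percent of the MEF value (quartiles 4.03 and 11.4), 4.96 in replicate 1 and 8.85 in replicate 2, and Xist kept 8.23 percent. Of these genes 81.8 percent lay within 3-fold of the median (77.6 percent at 2 standard errors lower), which did not decide whether iPSC still expressed selected fibroblast genes. On the same scale Junb kept 89.2 percent, Fos 46.3 and Jun 40.7, while Eln, at 2 and 6 in iPSC, kept 0.316 percent.

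OSK day 5 replicate 1 had Pou5f1 at 3.045 percent, Sox2 at 29.3 percent and Klf4 at 27.98 percent of replicate 2. Pou5f1 in replicate 2 stood at the highest value of the table, so its share may be overstated. Its correlation with replicate 2 was below its highest with a library of another group by a difference of -0.00809, too small to decide on a mislabelled sample. It had gone 79.4 percent of the way of replicate 2 from day 0 for the genes high in MEF. That would go against most cells lacking the factors only if cells without them kept these genes high. No course without factors was in the series, so the value did not decide on this. Its Xist stood at 21.6 percent of the lowest of the 21 other fibroblast-derived libraries (779 to 3617) and its summed Y-linked value at 1047, above their highest of 952, which did not decide on another preparation of fibroblasts with fewer female cells, as that idea came from the same values.

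The differences of OSK+shSap30 from OSK day 7 were weighed as a delay along the OSK course or as another batch. Of the 1580 called genes, 18.4 percent (290 genes) lay over 1 log2 outside the span of the OSK days, against 18.6 percent of the 1891 genes called with added Jun at day 7, which did not decide on a delay. Of the 3052 genes at least 1 log2 apart between OSK day 5 and day 7, called or not, 10.6 percent lay as far outside the span of the other OSK days at day 5. Its replicate differences correlated with those of the course groups by a mean of -0.0239, which did not separate batch from hairpin, since no control hairpin was in the series.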
